A study of Mus musculus with 6 samples.

How the data were processed

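Gene expression was measured in whole spleen of 6 Balb/c mice that were 6 to 8 weeks old. The 6 mice are labelled as female, which Xist and Y-linked genes argue against (see Other observations). Of the mice, 3 were untreated and 3 had received perfluorooctane sulfonate (PFOS), a persistent fluorinated surfactant, by stomach tube. The dose was 10 mg per kg body weight per day for 3 weeks. Per the labels' protocols, total RNA was extracted with Trizol, 6 ug was made into biotin-labelled cRNA, and each sample was hybridized to 1 Affymetrix Mouse430_2 array. The deposited values are on a log2 scale and come from RMA, per the submitters' processing notes. RMA corrects background, equalizes the probe distributions of the arrays and summarizes the probes of each probe set. Its version, and any filter or test used by the authors, are not given in the sources used here. Scanner files and detection calls were not used here, so no probe set could be called present or absent. Because RMA equalizes the arrays, every change reported is relative to the overall distribution of an array and not an absolute amount per cell.

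The table held 45101 probe sets. Of these, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in the platform annotation. Of the probe sets, 34754 carried an identifier that matched the gene table of assembly GRCm38.p6, and no symbol changed on update. The assembly served for names only, and no coordinates are given because the sources used here name no genome build.

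Control probe sets and those without a single gene symbol were left out of the gene tests. Probe sets whose mean over the 6 arrays lay under the 40th percentile of all non-control probe sets, a log2 value of 5.62, were left out too. The probe set with the highest mean over the 6 arrays then stood for its gene, which left 13101 genes. PFOS was compared with control with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05. Errors of changes are limma's standard errors (SE), and all groups had 3 arrays. The number of arrays limits the precision.

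Lists of genes, 44 in all, were written before the data were examined, as were the design, the rule for named genes and most of the other settings tried. They cover responses to foreign chemicals and stress, cell machinery, the cell types of the spleen, and tissues that could be carried along. Of 1222 entries, 988 were measured, which stand for 917 genes. Each list was tested with limma's camera at its preset correlation of 0.01, which compares the members with all other genes, and adjusted over the lists. Camera was repeated with the correlation estimated for each list, where the 6 arrays leave few degrees of freedom. Limma's fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes.

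The rule named the 12 genes with the largest rise and the 12 with the largest fall among called genes whose arrays did not overlap between groups. It also named up to 4 members with the smallest p in each called list and in 11 lists chosen beforehand. Array control probe sets were compared with an exact two-sided permutation test, which cannot give less than p = 0.1 with 3 arrays against 3.

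The procedure was tested on simulated data for this comparison, with 13101 genes at the levels and spreads of these arrays and 200 changed genes. Limma recovered 100% of changes of 1 on the log2 scale, 94% of changes of 0.5, 62% of changes of 0.25 and 6% of changes of 0.1, with 8 false calls. Of 40 simulated lists, camera called both shifted lists in the right direction and 0 of the others. The simulated noise was independent between genes, and far fewer genes changed than were called in the real arrays. These figures therefore do not measure the error or recovery of limma or camera in the real arrays.

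The labels call the arrays biological replicates 1 to 3 in each group. The main comparison did not use these numbers as pairs. Alternatives covered the replicate block, the filter, the scaling of arrays, the variance prior, array weights, the choice of probe sets, the threshold, the list test and leaving out each array.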

Results

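The study asked which transcripts of the spleen differ after PFOS exposure, as a way into its toxic mechanism. RMA log2 values of 3 control and 3 PFOS spleens were compared, and the median probe set lay between 6.15 and 6.18 on every array. Over the 13101 genes tested, arrays correlated at 0.9985 to 0.9991 within a group and at 0.969 to 0.970 between groups. The first principal component held 94.8% of the variance and separated the groups. The median within-group SD was 0.037 in control and 0.039 in PFOS on the log2 scale. The labels call the arrays biological replicates, and the p-values measure only this spread, which may be technical.

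Exposure to PFOS went with a large fall of a limited set of genes and a small rise of many others. Limma called 8730 genes, or 66.6% of those tested, of which 5324 were higher and 3406 lower in PFOS. The median size of a called change was only 0.23 on the log2 scale. Among the 391 called genes that changed at least 2-fold, 382 were lower and 9 higher, so that 97.7% of these were falls in the deposited values. Of the 12 largest falls, all but that of the pigment gene Dct were in genes of liver proteins and enzymes. By list median, the Liver list fell most, followed by red cell precursors and mitosis. The genes that rose were led by the immunoglobulin A heavy chain and included markers of T cells, B cells and red pulp macrophages. Every PFOS array lay above every control array for 5240 of the higher genes, and every PFOS array lay below every control array for 3363 of the lower genes. Groups did not overlap for 71.1% of all tested genes, where chance gives 10%. The split of calls depends on scaling: 61.0% of calls were higher in the deposited values and 39.9% when arrays were scaled on ribosomal protein genes. When they were scaled on the labelling spikes, a setting chosen after seeing the data, 95.5% of calls were higher, and 933 genes were at least 2-fold higher and 108 at least 2-fold lower.

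**Figure D1:**
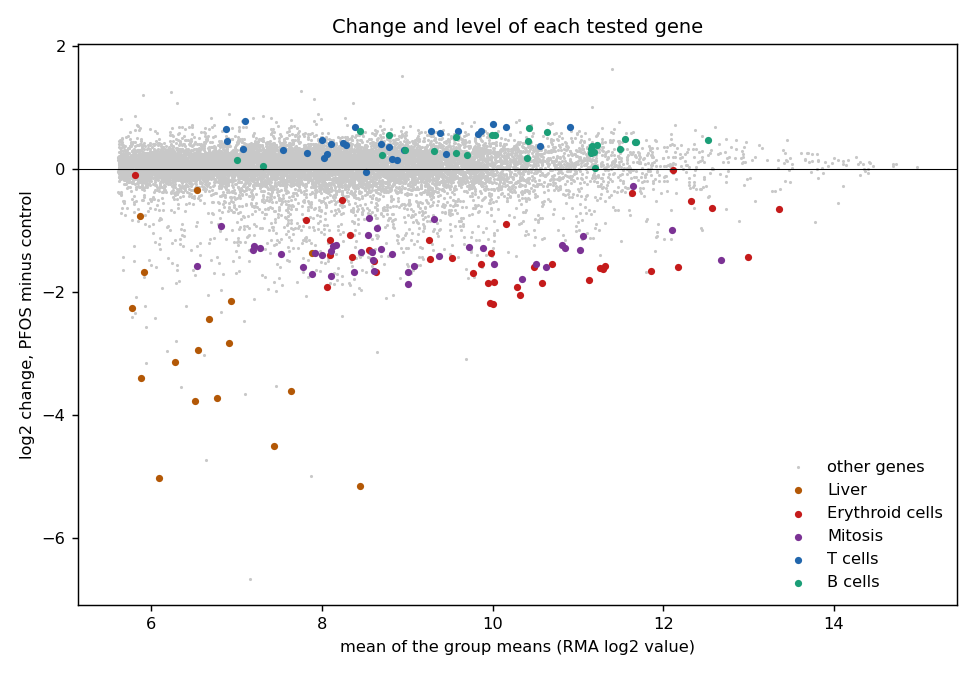
Log2 change (PFOS minus control, vertical axis) against the mean RMA log2 value of both groups (horizontal axis) for each of 13101 genes, with 5 gene lists in colour. The Liver, Erythroid cells and Mitosis members lie below 0, and nearly all T and B cell members above it.

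Transcripts made by liver cells fell more than any other list. All 17 measured members of the Liver list were lower, 15 of them at least 2-fold, with a median change of -2.95 (7.72-fold lower; camera adjusted p = 1.73e-13, and adjusted p = 0.017 with an estimated correlation). Alb, which encodes serum albumin, went from 11.03 in control to 5.87 in PFOS, a log2 change of -5.15 ± 0.04 (SE; limma adjusted p = 1.26e-09). Saa1, an acute phase protein, went from 10.50 in control to 3.82 in PFOS (limma adjusted p = 4.53e-10), where the latter lies under the filter floor of 5.62. Fibrinogen chains Fga and Fgg changed by -5.02 ± 0.11 and -3.78 ± 0.11. The apolipoproteins Apoa1, Apoa2 and Apoc3 changed by -3.73 ± 0.03, -3.62 ± 0.07 and -3.41 ± 0.04. Hpx, the haem-binding plasma protein hemopexin, changed by -4.51 ± 0.11, the protease inhibitor chain Itih4 by -3.55 ± 0.08, and Bhmt, a betaine methyltransferase of liver and kidney, by -3.67 ± 0.06. Apoh fell by 2.16 on the log2 scale, and its other probe set had the opposite sign. Dct, an enzyme of pigment synthesis, changed by -3.53 ± 0.14. The PFOS means of 12 of the 17 Liver genes, and those of Saa1, Itih4 and Bhmt, were under the filter floor of 5.62. The size, error and order of their changes thus depend on the background of the array. Such a gene passed the filter only if its control mean was above the floor, which fixed its change as a fall. The count of lower Liver genes and the list's camera p therefore rest in part on the filter.

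Red cell precursor genes fell together. Of 39 measured Erythroid members, 37 were lower, 30 of them at least 2-fold, and 2 (Xk and Bpgm) were not called; the median change was -1.50, or 2.84-fold lower (camera adjusted p = 1.84e-25, and adjusted p = 0.017 with an estimated correlation). Klf1, the master transcription factor of red cell development, changed by -2.05 ± 0.02 (limma adjusted p = 4.17e-09). The membrane proteins Kel, Cldn13 and Ank1 changed by -2.18 ± 0.02, -2.20 ± 0.03 and -1.85 ± 0.02. Of 15 measured Haem biosynthesis genes, 14 were lower, with a median of -1.16 (camera adjusted p = 6.51e-11, but adjusted p = 0.064 with an estimated correlation). Among them were the enzymes Alad (-1.86 ± 0.02), Urod (-1.58 ± 0.02) and Cpox (-1.41 ± 0.02) and the mitochondrial transporter Abcb10 (-1.76 ± 0.04). Alad, Urod, Cpox, Alas2, Uros, Ppox, Fech, Slc25a37 and Slc25a38 are also members of the Erythroid list, so the haem result is not independent of it.

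Genes of the cell cycle fell in the same arrays. All 42 measured Mitosis genes were lower, 37 of them at least 2-fold, with a median change of -1.35 or 2.55-fold (camera adjusted p = 4.39e-27, and adjusted p = 0.027 with an estimated correlation). All 40 measured DNA replication and S phase genes were lower too, 23 of them at least 2-fold, with a median of -1.02 or 2.02-fold (camera adjusted p = 1.17e-23, and adjusted p = 0.017 with an estimated correlation). Mki67, the proliferation marker, went from 13.41 to 11.93 (log2 change -1.48 ± 0.02). The cyclins Ccnb2 and Ccna2 changed by -1.87 ± 0.03 and -1.55 ± 0.02, and the ubiquitin carrier Ube2c by -1.59 ± 0.02. In the replication list, cyclin E2 (Ccne2) changed by -2.39 ± 0.03, the ribonucleotide reductase subunit Rrm2 by -1.68 ± 0.02 and the helicase subunit Mcm6 by -1.38 ± 0.02. Mcm10 changed by -1.43 ± 0.02, while its other probe set differed by 0.012 (limma adjusted p = 0.771).

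**Figure D2:**
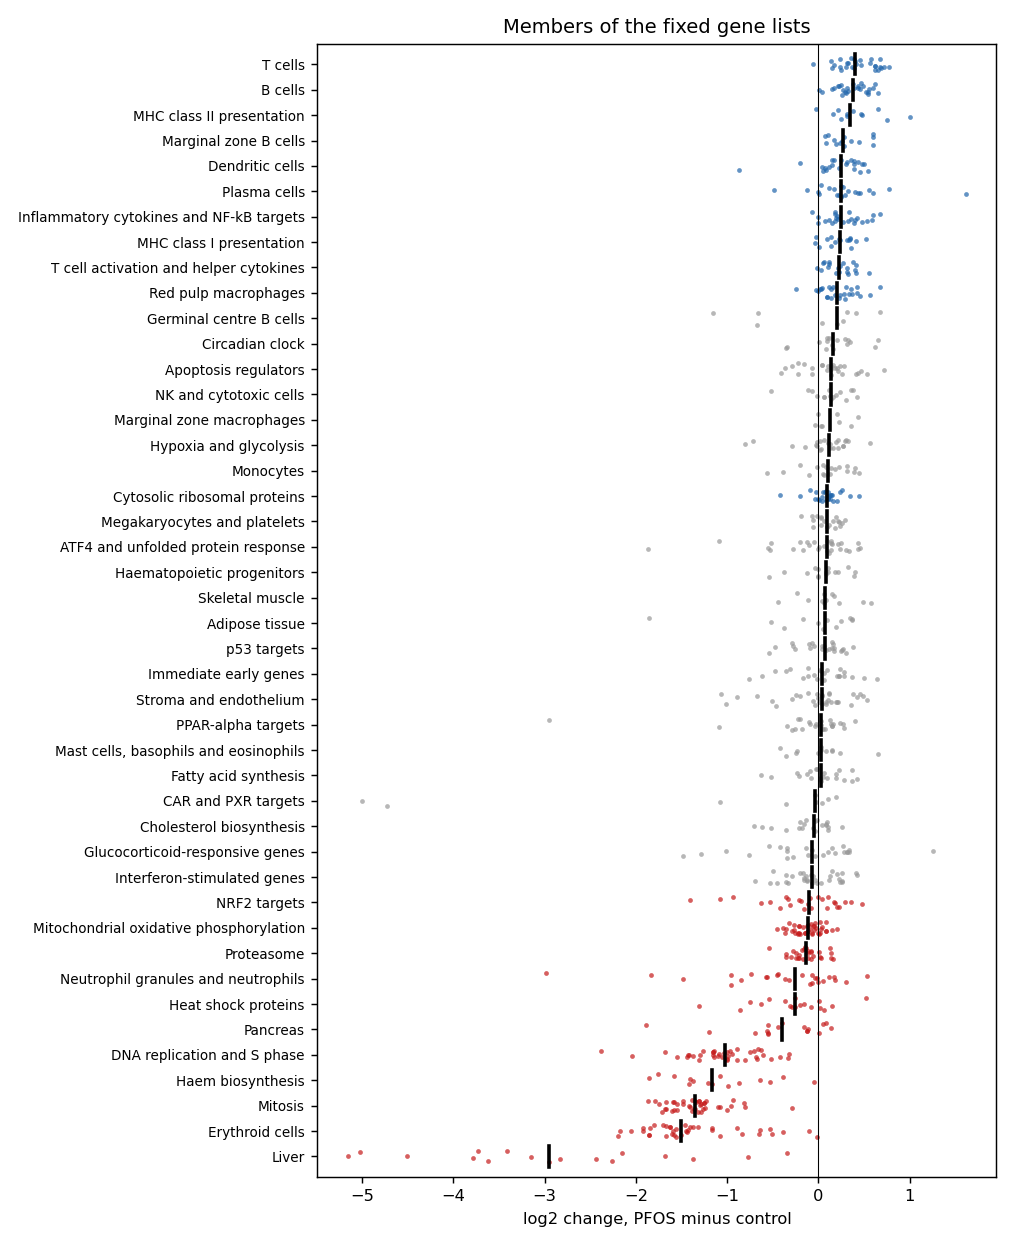
Log2 change (PFOS minus control, horizontal axis) of each measured member (points) of the 44 gene lists fixed beforehand, with the list median as a black bar. Red lists were called lower and blue lists higher by camera, and grey lists were not called; medians run from -2.95 for Liver to 0.41 for T cells.

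Lymphocyte markers were higher by a smaller amount. Of 29 measured T cell markers, 28 were higher and 0 lower, with a median rise of 0.41 or 1.32-fold (camera adjusted p = 2.34e-08, and adjusted p = 0.027 with an estimated correlation). The T cell receptor chains Cd3d and Cd3g rose by 0.68 ± 0.02 and 0.62 ± 0.02, the transcription factor Bcl11b by 0.72 ± 0.02 and the interleukin 7 receptor Il7r by 0.68 ± 0.02. Of 27 B cell markers, 25 were higher and 0 lower, with a median of 0.38 or 1.30-fold (camera adjusted p = 1.75e-07, but adjusted p = 0.067 with an estimated correlation). Cd79a, part of the B cell receptor, rose by 0.62 ± 0.02, Blk by 0.54 ± 0.02, Swap70 by 0.66 ± 0.02 and Fcer2a by 0.52 ± 0.02. Marginal zone B cell markers were higher in 13 of 14 cases (median 0.27, camera adjusted p = 0.000487, but adjusted p = 0.064 with an estimated correlation), with Cr2 at 0.60 ± 0.03 and Plac8 at 0.45 ± 0.03. Plasma cell genes were higher in 17 of 22 cases and lower in 2 (median 0.25, camera adjusted p = 0.00132, but adjusted p = 0.064 with an estimated correlation). Igha, the immunoglobulin A heavy chain, had the largest rise of all tested genes at 1.61 ± 0.02 (limma adjusted p = 1.09e-08), and its other 2 probe sets went the same way. Mzb1, a chaperone of antibody assembly, rose by 0.60 ± 0.02, Tnfrsf13b by 0.55 ± 0.02 and Eaf2 by 0.77 ± 0.04. With scaling on the labelling spikes, camera lost the calls of Marginal zone B cells (adjusted p = 0.156) and Plasma cells (0.199). That scaling adds the same constant to every change, so the place of these lists among the other genes did not move.

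The lists of T cell activation, antigen presentation, red pulp macrophages, dendritic cells and inflammatory genes were also called higher. Of 20 measured activation and helper cytokine genes, 16 were higher and 0 lower (median 0.23, camera adjusted p = 0.000975, but adjusted p = 0.064 with an estimated correlation). The 4 not called were the interleukins Il17a (0.06) and Il9 (0.03), with Il2ra (-0.02) and Cd40lg (0.06). The list median lay under that of the T cell markers (0.41), so the list did not rise beyond them. The costimulator Icos rose by 0.41 ± 0.02, Stat6, the signal transducer of interleukin 4, by 0.41 ± 0.02, Nfatc1 by 0.56 ± 0.03 and Cxcr3 by 0.40 ± 0.03. MHC class II genes were higher in 11 of 12 cases (median 0.35, camera adjusted p = 0.00045, but adjusted p = 0.064 with an estimated correlation). The largest rises were those of H2-DMb2 (1.00 ± 0.03), H2-Oa (0.75 ± 0.03) and Cd74 (0.65). H2-DMa (0.48 ± 0.02) and H2-Eb1 (0.47 ± 0.02) were named for their small p. MHC class I genes were higher in 13 of 16 cases (median 0.23, camera adjusted p = 0.00275, but adjusted p = 0.139 with an estimated correlation), including H2-M3 (0.52 ± 0.03) and H2-D1 (0.41 ± 0.02). Red pulp macrophage genes were higher in 20 of 26 cases and lower in 1 (median 0.21, camera adjusted p = 0.000575, but adjusted p = 0.064 with an estimated correlation). Spic, the transcription factor of these iron-recycling cells, rose by 0.57 ± 0.03, Vcam1 by 0.68 ± 0.02 and Mertk by 0.45 ± 0.02. Dendritic cell genes were higher in 17 of 23 cases and lower in 2 (median 0.25, camera adjusted p = 0.00275, but adjusted p = 0.067 with an estimated correlation), with Itgax at 0.55 ± 0.03 and Dpp4 at 0.48 ± 0.03, while Cd24a, which red cell precursors also carry, fell by 0.87. Inflammatory and NF-kB genes were higher in 19 of 24 cases and lower in 1 (median 0.25, camera adjusted p = 0.000213, but adjusted p = 0.080 with an estimated correlation), with Traf1 at 0.60 ± 0.02, Cd40 at 0.58 ± 0.02 and Birc3 at 0.53 ± 0.02. With scaling on the labelling spikes, each of these 6 lists lost its camera call, with adjusted p from 0.0946 (Red pulp macrophages) to 0.439 (Dendritic cells). Their place among the other genes was again unchanged by the constant added.

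**Figure D3:**
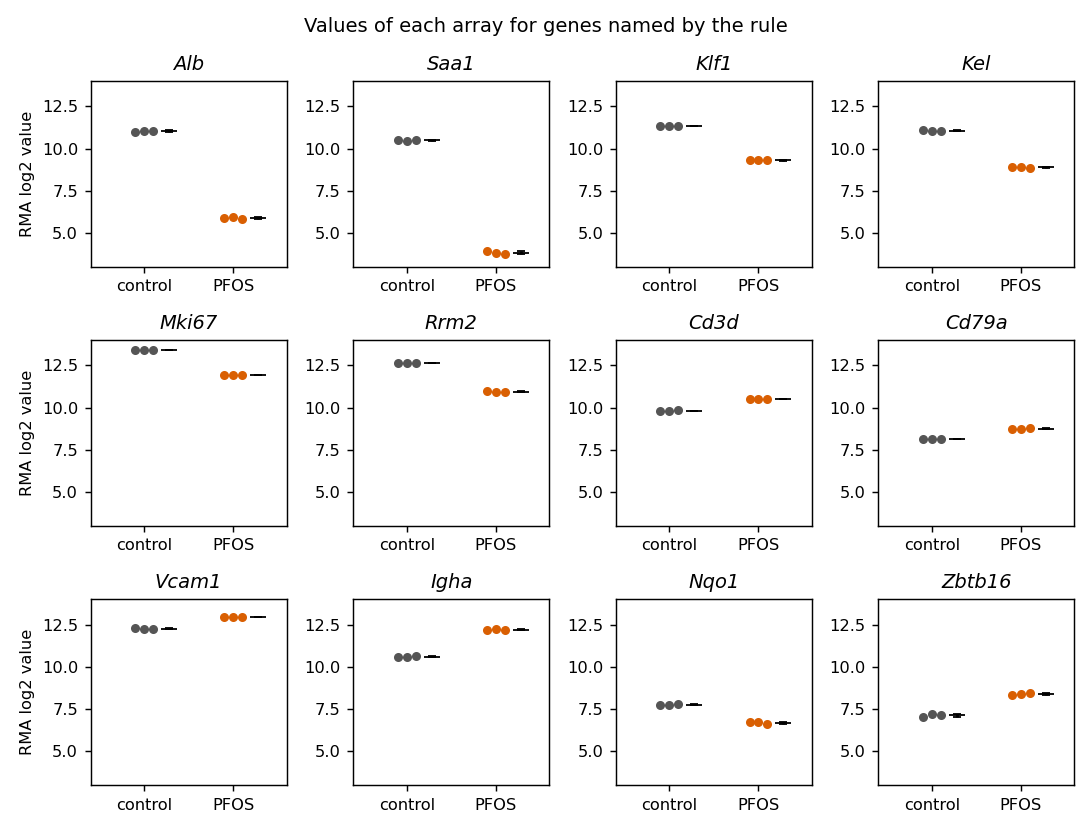
RMA log2 values (vertical axis) of the 3 control arrays (grey) and the 3 PFOS arrays (orange) for 12 genes, with the group mean and SD in black beside them. The arrays of a group lie close together in every panel, with Alb at 11.03 in control and 5.87 in PFOS and Igha at 10.59 and 12.21.

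Several further lists were called lower by smaller amounts. Neutrophil genes were lower in 15 of 26 cases and higher in 5 (median -0.25, camera adjusted p = 0.000374, but adjusted p = 0.064 with an estimated correlation). Hp, at -2.98 ± 0.03, and Lcn2, at -1.48 ± 0.04, are acute phase proteins that the liver also makes, and the granule proteins Camp and Ngp fell by 0.96 and 0.84. NRF2 targets were lower in 13 of 26 cases and higher in 8 (median -0.10, camera adjusted p = 0.038, but adjusted p = 0.139 with an estimated correlation). Both subunits of the enzyme that starts glutathione synthesis fell, Gclm by 1.40 and Gclc by 0.93, as did the quinone reductase Nqo1 by 1.08 and the transketolase Tkt by 0.53. The call of the NRF2 targets was lost with a stricter filter (adjusted p = 0.053), scaling on ribosomal protein genes (0.0997), a test on ranks (0.078), scaling on the labelling spikes (0.0996) and without _s_at, _x_at and _a_at probe sets (0.110, with a median of -0.035). Heat shock genes were lower in 12 of 18 cases and higher in 3 (median -0.26, camera adjusted p = 0.000487, but adjusted p = 0.139 with an estimated correlation), with Dnajb1 at -1.30 ± 0.03, Dnaja1 at -0.86 ± 0.04 and Hsph1 at -0.75 ± 0.03. Respiratory chain genes were lower in 25 of 42 cases and higher in 4 (median -0.11, camera adjusted p = 0.00012, but adjusted p = 0.067 with an estimated correlation), with Ndufb9 at -0.45 ± 0.02. Proteasome genes were lower in 19 of 29 cases and higher in 4 (median -0.14, camera adjusted p = 0.000491, but adjusted p = 0.064 with an estimated correlation), with Psmd1 at -0.54 ± 0.02. Pancreas genes were lower in 10 of 17 cases and higher in 1 (median -0.40, camera adjusted p = 0.000952, but adjusted p = 0.139 with an estimated correlation), with the colipase Clps at -1.88 ± 0.11 and Cela1 at -0.55 ± 0.03. Pancreas was listed as a tissue that could be carried along, and whether it was carried into the control samples was not tested. Cytosolic ribosomal proteins were higher in 20 of 30 cases and lower in 3 (median 0.10, camera adjusted p = 0.046, but adjusted p = 0.139 with an estimated correlation), a call lost with replicate blocks (adjusted p = 0.057), without the filter on low values (0.055), with arrays centred on their median (0.058), quantile normalization (0.522), scaling on ribosomal protein genes (0.335), a test on ranks (0.052), without _s_at, _x_at and _a_at probe sets (0.998, direction turned), without hepatocyte genes (0.0501) and without control replicate 2 or 3 or PFOS replicate 1, 2 or 3 (adjusted p from 0.054 to 0.065). With scaling on the labelling spikes, camera lost the calls of Heat shock proteins (adjusted p = 0.053), ribosomal proteins (0.0996), Mitochondrial oxidative phosphorylation (0.420) and Proteasome (0.694). The camera direction of the last 2 also turned, but their medians (0.529 and 0.506) stayed under the median of all genes (0.692). This scaling adds the same constant to every change and so moves no list against the other genes. Camera works on each gene's change over its error, and the constant alters that ratio unequally. Whether this cost the calls was not tested.

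The nuclear receptor lists did not pass the list test. PPAR-alpha is a receptor that perfluorinated acids can activate in the liver. Of its 26 measured targets, 9 were higher and 8 lower (median 0.03, camera adjusted p = 0.538). The mean was -0.14, so median and mean differed in sign, as median and mean or test did in 6 other uncalled lists. Fabp1, the liver fatty acid binding protein, fell by 2.95, Angptl4 by 0.28, and Aldh3a2 rose by 0.41 ± 0.04. Mgll fell by 1.09, but 1 of its 3 other probe sets went the other way. Of 9 measured CAR and PXR targets, 4 were lower and 2 higher (median -0.03, camera adjusted p = 0.056). CAR and PXR targets passed without the filter on low values (adjusted p = 0.0028), with array weights (0.042), with the mean over probe sets (0.048), with scaling on the labelling spikes (0.00025), without _s_at, _x_at and _a_at probe sets (0.026) and without control replicate 1 (0.041) or PFOS replicate 1 (0.031). The adjusted p was 0.158 with an estimated correlation, 0.371 with a stricter filter (median 0.0070) and 0.407 with hepatocyte genes left out, a setting chosen after seeing the data. The largest falls there were the drug-metabolizing liver enzymes Cyp2c29 (10.38 in control and 5.37 in PFOS) and Cyp3a11 (9.01 and 4.28), whose PFOS levels, like that of Fabp1 (4.71), lie under the filter floor, with Aldh1a1 at -1.08 ± 0.02 and Cyp2b10, the classic CAR target, at -0.36 ± 0.04. Of 24 p53 targets, 12 were higher and 6 lower (median 0.07, camera adjusted p = 0.911), with the repair gene Xpc at 0.38 ± 0.03 and Gtse1, a gene of dividing cells, at -0.54 ± 0.04. Adjusted over the list alone, the count of lower genes was 7 for p53 targets and 20 for the proteasome; for the other 42 lists the counts adjusted over the list alone equalled those over all genes.

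The 12 genes with the largest rises were mostly outside the lists. After Igha came Casd1, an enzyme that acetylates sialic acid, at 1.51 ± 0.02 (limma adjusted p = 1.09e-08), and Zbtb16, the transcription factor PLZF of innate-like lymphocytes, at 1.26 ± 0.05 (limma adjusted p = 4.23e-07). Gm3715, Tmem255a, Cirbp, Tsga13 and Ntmt1 rose by 1.24 ± 0.07, 1.20 ± 0.06, 1.13 ± 0.04, 1.07 ± 0.07 and 1.06 ± 0.05. Cirbp encodes a cold-inducible RNA-binding protein, and the other probe set of Ntmt1 had the opposite sign. The remaining members were H2-DMb2, Scg5 (0.89 ± 0.04), a variable segment of the immunoglobulin kappa light chain (0.89 ± 0.06) and Zc3h6 (0.86 ± 0.06). The control means of Gm3715 (5.61), Tmem255a (5.30) and Zc3h6 (5.38) lie under the filter floor of 5.62, so the size and order of these rises depend on the background.

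Control probe sets gave a measure of RNA and labelling in the same arrays. The bacterial transcripts added to RNA before labelling were lower in PFOS, at a mean of 6.65 ± 0.01 (SD, n = 3) in control and 6.11 ± 0.02 in PFOS, a difference of -0.53 (exact permutation p = 0.1, the smallest possible). All 24 of their probe sets were lower. The mean of the transcripts added before hybridization did not separate the groups, at 10.00 ± 0.01 and 10.00 ± 0.01 (SD, n = 3, exact permutation p = 0.9). Of their 18 probe sets 8 were lower in PFOS, and for 6 every PFOS array lay below every control array. Differences of these probe sets ran from -0.22 to 0.09. Scaling on the labelling spikes, chosen after seeing the data, would add 0.64 to every log2 change; the medians of the Liver, Erythroid, Haem biosynthesis, Mitosis and S phase lists stay below 0 then, and those of the other 6 lists called lower turn positive. Camera then called 10 lists in place of 22: of the main calls, 11 were lost in the same direction and 2 with the direction turned. The constant leaves each list's place among the other genes as it was. Camera weighs each change by its error, and the scaling also shifted each array by its own amount, which alters those errors. Which of these cost the calls was not tested. The 3' minus 5' difference of actin, a sign of RNA length, was 2.03 in control and 2.21 in PFOS, and that of GAPDH was 1.74 and 1.69 (both exact permutation p = 0.1). The 5' probe set of 18S ribosomal RNA was lower in PFOS by 0.75 (12.79 against 12.04), while its 3' probe set differed by 0.02.

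**Figure D4:**
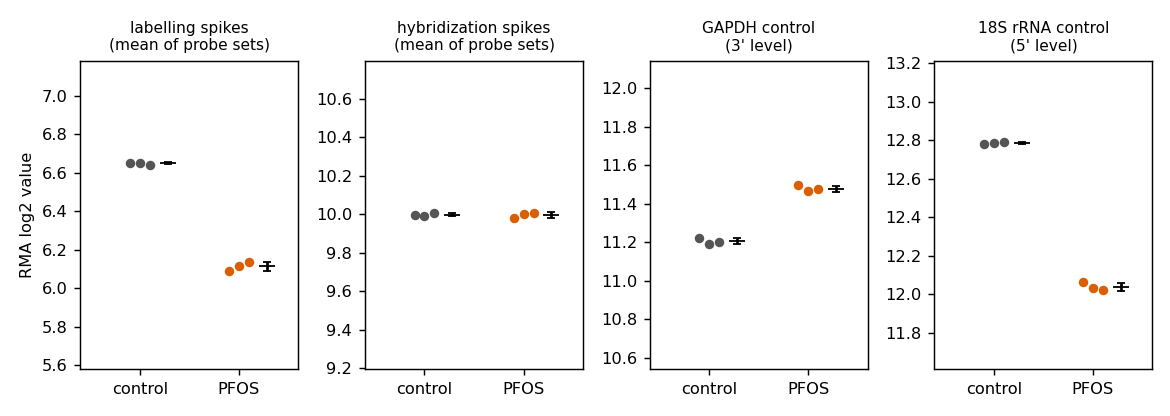
RMA log2 values (vertical axis, the same span of values in each panel) of control probe sets in the 3 control arrays (grey) and the 3 PFOS arrays (orange), with the group mean and SD in black. The labelling spikes are lower in PFOS (6.65 against 6.11), while the hybridization spikes lie at 10.00 in both groups.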

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

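All tests of explanations in this part were chosen after seeing the data: the list medians behind the comparison of T cell with stromal genes were already known, and the reading of the within-group spread was made stricter after its value was seen. Among 4588 probe sets that carry no single gene name and so took no part in the gene tests, limma called 1879 higher and 966 lower in PFOS, and 16 of them were at least 2-fold higher and 68 at least 2-fold lower. These 16 were singled out because they are a rise in data outside the gene tests. The probe set with the largest rise went from 6.43 ± 0.03 (SD) to 9.23 ± 0.06, and one that fell went from 14.33 ± 0.02 to 4.98 ± 0.26, under the filter floor of 5.62, so that the size of its fall depends on the background.

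The first pattern is the fall of liver transcripts. The hepatocyte list held 144 genes. Of 75 measured outside the Liver list, 64 (85.3%) were lower in PFOS and 5 higher, against 26.0% lower among all tested genes. A gene at background in PFOS passed the filter only if its control values were high, so the filter favours falls here. The share therefore cannot decide whether liver tissue or RNA was carried into the control samples. It also missed the 90% set for that explanation, which stays open, and 6 of the 75 genes are also held by another list. A lowering of these transcripts by the exposure within the spleen cannot be told apart from carried-over liver. No liver or sorted spleen sample is at hand. The median SD of the Liver list over the 3 control arrays was 0.054. With the hepatocyte genes left out, 5323 genes were higher and 3328 lower, 8644 of the 8730 genes were called, and 20 lists; the Liver list then has too few genes, and Cytosolic ribosomal proteins lost their call (adjusted p = 0.0501).

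The second pattern is the fall of erythroid and cell-cycle genes beside the rise of lymphocyte genes. Liver RNA diluting spleen RNA in the control samples would make spleen transcripts lower in control, whereas the Erythroid median was -1.50 (95% bootstrap interval over genes -1.62 to -1.37) in PFOS, which argues against it for the erythroid fall only. As the whole cause of the lymphocyte rise it would raise all spleen cell types alike. The T cell median exceeded that of megakaryocytes and platelets by 0.31 (95% bootstrap interval over genes 0.19 to 0.52). Those 2 lists did not rise alike, but both medians were known beforehand, and the interval resamples genes and not animals. The megakaryocyte list is also mixed, with 11 genes higher and 3 lower. It therefore cannot decide the matter, and such dilution as a cause of the lymphocyte rise stays open. A loss of erythroid cells alone would raise every other cell type alike. The T cell median exceeded the stromal and endothelial median by 0.36 (95% bootstrap interval over genes 0.26 to 0.56), with member quartiles of 0.30 to 0.62 and -0.21 to 0.19. These 2 lists thus did not rise alike. The stromal list is itself mixed, with 14 genes higher and 10 lower, from Col1a1 at -1.06 to Cxcl13 at 0.53. It therefore cannot show what such a loss alone would do, and that loss as the cause of the lymphocyte rise stays open. A smaller share of red cell precursors in the exposed spleens remains a hypothesis for the erythroid fall itself, and whether the cell-cycle genes fell in those cells or in others may not be settled from whole tissue.

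The third pattern is the closeness of arrays within a group. Labelling spikes above the filter floor differed by -0.62 between the groups and hybridization spikes by 0.01, with median within-group SDs of 0.04 and 0.02. A difference in labelling between the groups, such as separate reactions or different spike amounts, could give this, but other causes were not tested. Such a batch cannot be separated from the exposure in this design. The spike difference lies between the groups and does not measure the closeness within a group. Replicate 1 stood apart in both groups. On the second principal component it lay at 4.25 in control and 5.27 in PFOS, the other arrays at -2.91 to -2.02. Its array weights were 0.57 and 0.48, the others 1.27 to 1.52. Across groups, the replicate 1 arrays deviated together (correlation 0.324) and against replicates 2 and 3 (-0.226 to -0.177). Whether same-numbered arrays share a batch was not tested. Whether the arrays of a group share one RNA pool cannot be told apart from very uniform animals: immediate early genes, which respond to handling, had a within-group SD at the 73.6th percentile of expression-matched lists, while Liver genes in the control arrays lay at the 98.8th percentile, clock genes at the 50.98th, interferon genes at the 21.0th, and neutrophil and glucocorticoid-responsive genes both at 8.05. If they shared a pool, the p-values would describe 2 pools and not 6 animals.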

How the results depend on the processing

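The alternatives called scaling on labelling spikes, leaving out hepatocyte genes and a 1.5-fold threshold were chosen after seeing the data. Higher genes numbered 3327 when arrays were scaled on ribosomal protein genes (39.9% of calls), 10048 when probe sets were counted, 12264 when scaled on labelling spikes, 134 at 1.5-fold and 9 at 2-fold. Lower genes numbered 7112 as probe sets, 581 when scaled on labelling spikes, 783 at 1.5-fold and 382 at 2-fold. At least 2-fold, 31 probe sets were higher and 627 lower, and scaling on labelling spikes gave 933 higher and 108 lower. Counting probe sets raises the number of features to 27022. The spike scaling adds the same constant to every gene, which moves no list against the other genes. Camera called 22 lists, 5 with an estimated correlation and 10 when scaled on labelling spikes, and fry 41. With that scaling the sign turned for the camera direction of Mitochondrial oxidative phosphorylation (median 0.529, adjusted p = 0.420) and Proteasome (0.506, adjusted p = 0.694) and, by the constant added, for 17 named genes: Prss2 (0.085, adjusted p = 0.0848), Cela1 (0.095), Gtse1 (0.103, adjusted p = 0.0541), Psmd1 (0.106), Hspa4l (0.106), Tkt (0.111), Btg2 (0.167), Ndufb9 (0.188), Ndufv1 (0.249), Cyp2b10 (0.282), Cox6a1 (0.283), Psmc5 (0.283), Cox5b (0.316), Psmc3 (0.338), Angptl4 (0.358), Psmd4 (0.364) and Rps2 (0.437). With an estimated correlation the B cell list missed the threshold (median 0.38, adjusted p = 0.067). Without probe sets of the _s_at, _x_at and _a_at kinds the sign turned for the camera direction of the ribosomal list (median 0.059, adjusted p = 0.998) and for Mgll (0.158, adjusted p = 0.0036), while Mcm10 (0.012, adjusted p = 0.771) and Dtx1 (-0.071, adjusted p = 0.352) lost their calls and lay near 0; in fry the germinal centre list reversed (median 0.20); the cause was not tested. The ribosomal call was lost without control replicate 2 (adjusted p = 0.065) or 3 (0.060) and without PFOS replicate 1 (0.058), 2 (0.059) or 3 (0.054). Uncalled in the main setting of camera, Interferon-stimulated genes passed without the filter (adjusted p = 0.028), with a stricter filter (0.031), with array weights (0.049), without _s_at, _x_at and _a_at probe sets (0.047) and without PFOS replicate 1 (0.048). Cholesterol biosynthesis passed without the filter (0.033) and with a stricter one (0.043), and Circadian clock without the filter (0.037) and with the mean over probe sets (0.043). Leaving out each array gave 4824 to 5209 higher and 3112 to 3313 lower genes, 8 to 9 and 379 to 390 of them at least 2-fold, and 21 to 23 lists. List medians then ran from -1.55 to -1.47 (Erythroid), -1.38 to -1.31 (Mitosis), -1.05 to -1.01 (S phase), -3.00 to -2.90 (Liver), 0.39 to 0.41 (T cells) and 0.36 to 0.39 (B cells), all called. Same-numbered arrays deviated together at correlations of 0.324, 0.138 and 0.097, and control replicate 3 with PFOS replicate 2 at 0.128. The unpaired design was fixed beforehand. With the replicate block, 8550 of the 8730 genes were called too, and the ribosomal list was the only list to lose its call (adjusted p = 0.057). Of 2156 values of 116 named genes under 19 alternatives, 2132 kept direction and side of the threshold, 4 lost the call and 20 turned sign. The genes were named for large changes or small p in these same arrays, so most were bound to keep their calls. The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05: in 1 of them, the real one, 8730 genes were called, and the highest other split called 0 (33 to 133 genes at an unadjusted p under 0.05). For lists the real split was again the 1 highest, with 22 calls against 21 in another split; other splits keep part of the group difference, since 1 side holds 2 control arrays and the other 1. Values near the filter floor limit the folds of Liver genes.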

Other observations

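The genes in this and the next paragraph were chosen after their values were seen. Of 29 measured ATF4 and unfolded protein response genes 14 were higher and 9 lower (median 0.09, camera adjusted p = 0.988). Asparagine synthetase, Asns, changed by -1.87 ± 0.05 (SE), the amino acid transporter Slc7a5 by -1.09 ± 0.02 and Atf4 itself by -0.52 ± 0.03, while Xbp1 and Edem1, of the secretory pathway, rose by 0.43 ± 0.02 and 0.45 ± 0.03. Phgdh, of serine synthesis, rose by 0.43. Among glucocorticoid-responsive genes 10 were higher and 12 lower of 25 (median -0.07, camera adjusted p = 0.237): the metallothioneins Mt1 and Mt2 changed by -1.01 ± 0.03 and -1.28 ± 0.05, Fkbp5 by -0.11 ± 0.02 and Tsc22d3 by 0.10 ± 0.03, while Zbtb16, also in this list, rose by 1.26 ± 0.05. Stromal genes divided as well, with 14 higher and 10 lower of 33 (median 0.04, camera adjusted p = 0.911): the collagens Col1a1 and Col3a1 changed by -1.06 ± 0.09 and -1.01 ± 0.03 and the matrix protein Sparc by -0.89 ± 0.02, while the follicle chemokine Cxcl13 rose by 0.53 ± 0.02 and Tcf21 by 0.49 ± 0.03. Bcl2, which protects lymphocytes from death, rose by 0.72 ± 0.04, in a list of apoptosis regulators with 17 higher and 7 lower of 27 (median 0.14, camera adjusted p = 0.235). Clock genes were higher in 11 of 16 cases and lower in 2 (median 0.16, camera adjusted p = 0.083, passed under 2 other settings of camera), with Dbp at 0.65 ± 0.07 and Per1 at -0.35 ± 0.02. Interferon-stimulated genes, called lower under several other settings of camera (adjusted p from 0.028 to 0.049) but not with an estimated correlation (0.371), were higher in 11 and lower in 17 of 32 cases (median -0.07, camera adjusted p = 0.056), with Cmpk2 at -0.69 ± 0.05 and Ddx60 at 0.42 ± 0.05.

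The labels call the mice female, yet the 3 Xist probe sets lay between 3.71 and 5.86 on all 6 arrays, while the Y-linked Eif2s3y and Kdm5d reached 9.91 and 7.94 on their brightest probe sets, whose lowest values were 9.62 and 7.54. This held in control and PFOS arrays. The brightest Eif2s3y probe set lay at the 93.4th percentile of probe sets, while its other probe set lay between 3.31 and 3.40. These values argue against the female label for all 6 arrays. Of 2 pigment genes picked after their values were seen, the Tyrp1 probe set with the largest fall went from 7.68 ± 0.10 (SD) to 3.72 ± 0.06, under the filter floor of 5.62. Its 2 other probe sets were lower too, from 6.79 to 5.22 in one and from 5.55 to 4.40 in the other, also with PFOS means under the floor and, in the last, both means. Pmel went from 7.75 ± 0.03 to 6.31 ± 0.08. All 3 Igha probe sets rose, by 1.61, 1.60 and 1.43.

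The remaining lists did not pass camera in the main setting. Medians and adjusted p were 0.20 and 0.911 for germinal centre B cells (5 higher, 3 lower of 9, with Ezh2 at -1.15 ± 0.02 and Gcsam at 0.67 ± 0.10), 0.14 and 0.122 for NK and cytotoxic cells, 0.12 and 0.286 for marginal zone macrophages, 0.10 and 0.241 for monocytes, and 0.10 and 0.286 for megakaryocytes and platelets. They were 0.03 and 0.824 for mast cells, basophils and eosinophils, 0.09 and 0.729 for progenitors, 0.07 and 0.995 for adipose tissue, and 0.07 and 0.626 for skeletal muscle. They were 0.12 and 0.364 for hypoxia and glycolysis, 0.05 and 0.995 for immediate early genes, -0.05 and 0.056 for Cholesterol biosynthesis (0.033 without the filter and 0.043 with a stricter one), and 0.03 and 0.995 for fatty acid synthesis.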
